A study of Mus musculus with 8 samples.

How the data were processed

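Total RNA from 4 WT and 4 Cry DKO lines of primary mouse embryonic fibroblasts was measured on an Affymetrix 3' expression array, 1 array per line. Per the labels, cells grew in medium with 10% serum at 3% oxygen, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 5 ug of total RNA; embryos came from a near-C57BL/6J background after more than 7 backcrosses from BL6/129 mice. The deposited values are on a log2 scale. The base is inferred from the range of the values (0.0675 to 14.3) and is not given in the sources used here, so every fold below rests on it. GCOS, the Affymetrix array software, is named without a version in the submitters' processing notes. How probes were summarised, how arrays were normalised and how the listed probe sets were chosen are not given in the sources used here. The array medians nearly coincide (6.78 to 6.79), so the values were taken as normalised between arrays and used as deposited. A global change in RNA amount cannot be seen after such a normalisation. Groups and replicate numbers came from the sample titles, and no array duplicated another (0 identical columns).

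The table held 30506 probe sets, of which 61 were control probe sets. The platform's annotation table paired 24838 probe sets with 1 gene and 658 with several genes, and 4949 are unnamed here. Gene identifiers of 24757 of the 24838 were found in the annotation of assembly GRCm38.p6, which was used only for symbols and for which genes neighbour each other, since no build is named for the array. Control, unnamed and several-gene probe sets were left out, as were probe sets with a mean over the 8 arrays below the 40th percentile (6.05, called the floor here). Each gene was represented by its probe set of highest mean, which gave 9515 genes. No detection calls were used. Signal over background limits the precision: the median within-group SD was 0.55 for probe sets with a mean under 5 and 0.10 for those over 9, on the log2 scale. Probe sets of 1 gene passed in opposite directions for Tpbg alone (0.80 and 0.47 against -1.28).

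Genotypes were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, no covariate and Benjamini-Hochberg adjustment over all tested genes, with an adjusted p of 0.05 as threshold. The p-values measure the spread between independent lines. Cry1 and Cry2 were also compared with exact two-sided permutation tests. A set of 30 gene lists was fixed before the data were examined: clock genes activated through E-boxes, the positive arm of the clock and RORE targets, DNA replication and S phase, G2 and mitosis, CDK inhibitors and G1 cyclins, p53 targets, hypoxia (HIF) targets, collagens and fibroblast extracellular matrix, smooth muscle and contractile genes, TGF-beta targets, cAMP-CREB and immediate early genes, glucocorticoid receptor targets, NF-kappaB and inflammatory cytokines, interferon-stimulated genes, MYC targets and ribosome biogenesis, cholesterol synthesis, unfolded protein response and ATF4 targets, NRF2 and oxidative stress genes, HOX genes, imprinted growth genes, circadian bZIP output and drug metabolism genes, Y-linked genes, and markers of endothelial cells, macrophages and blood cells, epithelium, skeletal muscle, neural and glial cells, adipocytes, cartilage and bone, and erythroid and liver cells. The 26 lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance 1 way, were alternatives. With an estimated correlation the calls of 3 lists held: the E-box clock genes, DNA replication and mitosis. Genes within 10 Mb of Cry1 or Cry2 were compared with all others in Fisher's exact test.

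Genes are named by a rule fixed before the data were examined: Cry1 and Cry2; the 12 highest and 12 lowest differences among called genes whose groups do not overlap; every called member of the 2 clock lists, with Per1, Per2, Nr1d1, Dbp and Arntl in any case; from each other list up to 4 members of smallest p where the list passed or held a called gene, and up to 2 otherwise; and called genes within 10 Mb of Cry1 or Cry2. Members named outside it were chosen after their values were seen: Leo1, Clock, Cdkn2a and Cdk2.

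The scripts were tested on simulated data with the real means and spreads of the 9515 genes, 5 runs with 200 changed genes each. For the Cry DKO and WT comparison, 69% of genes changed by 0.5 on the log2 scale were called, 94.9% of those changed by 1 and 99.7% of those changed by 2, and 0.0966% of unchanged genes. Simulated genes were drawn independently of each other. These rates therefore do not cover differences between lines that many genes share, as in the real arrays. Alternatives were a replicate block, other normalisations, filters, probe set rules and empirical Bayes settings, array weights, Student's equal-variance test, other thresholds, and each array left out in turn. Terms for the sex of the line and for macrophage markers were added after seeing the data. A pseudocount was not varied because the values are already logarithms.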

Results

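Gene expression was measured in primary mouse embryonic fibroblasts, cells grown directly from embryos and not immortalised, from wild-type embryos and from embryos lacking both cryptochrome genes, Cry1 and Cry2. Cryptochromes are the repressors of the circadian clock that hold back the transcription factor pair CLOCK and ARNTL. There were 8 arrays, 4 from wild-type (WT) lines and 4 from Cry1 and Cry2 double-knockout (Cry DKO) lines, and each array came from an independent cell line. The cells were proliferating without synchronisation at 3% oxygen, so each value averages over cells at any clock phase and any point of the cell cycle. Array medians lay between 6.78 and 6.79 on the log2 scale, and correlations between arrays of 1 genotype (0.973 to 0.977) lay close to those between genotypes (0.967 to 0.975). The number of arrays limits the precision: the median within-group SD of a tested gene was 0.13 on the log2 scale. All differences below are Cry DKO minus WT on the log2 scale, with n = 4 lines per genotype, values as mean ± SD where both groups are given, and SE for differences. Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

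The targeted genes were read first. Cry1 had a signal of 6.79 ± 0.40 (SD, n = 4) in WT lines and 6.29 ± 0.31 in Cry DKO lines, a difference of -0.50 (SE 0.21, adjusted p = 0.168 by limma). Cry2 had 7.20 ± 0.18 in WT and 6.87 ± 0.20 in Cry DKO lines, a difference of -0.34 (SE 0.13, adjusted p = 0.132 by limma). In exact two-sided permutation tests over the 70 assignments of 4 and 4 lines, p was 0.114 for Cry1 and 0.0571 for Cry2, where the smallest possible value is 0.0286. Neither difference passed, and the groups overlapped for both genes. Where the probes of these probe sets lie relative to the deleted parts of the genes is not given in the sources used here, so the 2 values do not check the genotype labels.

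The first comparison asked which genes differ between Cry DKO and WT fibroblasts. The genes with the highest increases included clock genes: Per2, a partner of the cryptochromes in clock repression, rose from 5.53 ± 0.29 (SD, n = 4) to 8.37 ± 0.10, a difference of 2.84 (SE 0.14, limma adjusted p = 3.37e-06). Dbp, a clock-controlled transcription factor, rose by 2.21 (SE 0.12, adjusted p = 4.16e-06), and Ciart, a repressor of the clock, rose by 1.80 (SE 0.14, adjusted p = 8.7e-05). Fcgr2b, an Fc receptor of immune cells, rose by 3.04 (SE 0.37, adjusted p = 0.00156), from 6.39 ± 0.96 to 9.43 ± 0.29, and Rbm45, an RNA-binding protein, rose by 2.95 (SE 0.22, adjusted p = 6.15e-05). The size of the Fcgr2b rise depends on the probe set. Its other probe sets gave 1.61, 2.48 and 2.94. Without Cry DKO replicate 1, where the probe set with the lowest of these represents the gene, it was 1.58. The other genes among the 12 highest were 2010315B03Rik (1.53), Trem2 (1.32), a receptor of macrophages and microglia, Srgn (1.21), a proteoglycan of blood cell granules, C5ar1 (1.20), a complement receptor, Clec4d (1.19), a lectin of myeloid cells, Cd36 (1.14), a fatty acid receptor, and Lars2 (1.12), a mitochondrial leucyl-tRNA synthetase. WT lines had 2010315B03Rik, Per2 and Trem2 below the floor used to select genes, where dim signals are less precise (WT SD 0.80, 0.29 and 0.44). Leaving out 1 array ended the call of Trem2 in 3 and that of 2010315B03Rik in 1 of 8 fits. The macrophage and blood cell marker list rose in the same lines, with a median change of 0.74.

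Among the lowest, Pgm5, a protein of adhesion sites in muscle, fell by 1.90 (SE 0.30, adjusted p = 0.00411 by limma), and Parm1 fell by 1.69 (SE 0.21, adjusted p = 0.00156). Thg1l, a tRNA-histidine guanylyltransferase-like protein, fell by 1.61, and Arntl, the partner of CLOCK, fell by 1.56 (SE 0.11, adjusted p = 3.64e-05). Igfbp5, a binding protein of insulin-like growth factors, fell by 1.54, Tcfl5 fell by 1.44 and Ramp1, a receptor-modifying protein, fell by 1.37. Nnat fell by 1.35, Rspo2, an enhancer of Wnt signalling, fell by 1.25, Adamts4, a protease of proteoglycans, fell by 1.23, Cdkn1c, an inhibitor of cyclin-dependent kinases, fell by 1.17, and Dcaf12l1 fell by 1.16. Pgm5 and Thg1l lay below the floor in Cry DKO lines. Leaving out 1 array ended the call of Tcfl5 in 2 and that of Dcaf12l1 in 3 of 8 fits.

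Of 9515 genes tested, 873 passed an adjusted p of 0.05 in limma, 471 higher and 402 lower in Cry DKO lines. Most changes were small, with a median size of 0.42, and 25 of the called genes rose and 21 fell by at least 2-fold. The groups did not overlap for 819 of the 873, and for 16.8% of all tested genes, where chance gives 2.86%. The count fell whichever line was left out, which also leaves fewer samples, and the size of the fall differed between lines. The count was 386 without WT replicate 3, 472 without WT replicate 2, 491 without WT replicate 1 and 591 without WT replicate 4. It was 555 without Cry DKO replicate 2, 570 without Cry DKO replicate 3, 636 without Cry DKO replicate 4 and 684 without Cry DKO replicate 1. It was 317 when each gene was tested on its own spread alone, 520 with the sex of the line as a term and 51 with the mean of the macrophage markers as a covariate, a measure that itself differs between the genotypes; the last pair were chosen after seeing the data.

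Clock genes activated through E-boxes, the DNA elements bound by CLOCK and ARNTL, rose together. Of 12 tested members 10 rose and none fell, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.89e-15, and adjusted p = 0.00338 with an estimated correlation). Besides Per2, Dbp and Ciart, the nuclear receptor Nr1d2 rose by 0.98 (SE 0.05, limma adjusted p = 4.16e-06) and the transcription factor Tef by 0.97. Per1 rose by 0.79 (SE 0.20, limma adjusted p = 0.0338), Tspan4 by 0.56, the repressor Bhlhe40 by 0.54, the kinase Wee1 by 0.48 and the NAD-synthesis enzyme Nampt by 0.45. Nr1d1, which represses Arntl, had a difference of 0.50 (SE 0.14, limma adjusted p = 0.0521), and Leo1 one of -0.28 (adjusted p = 0.127). The call of Per1 ended in 4 of the 8 fits that leave out 1 array.

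**Figure D1:**
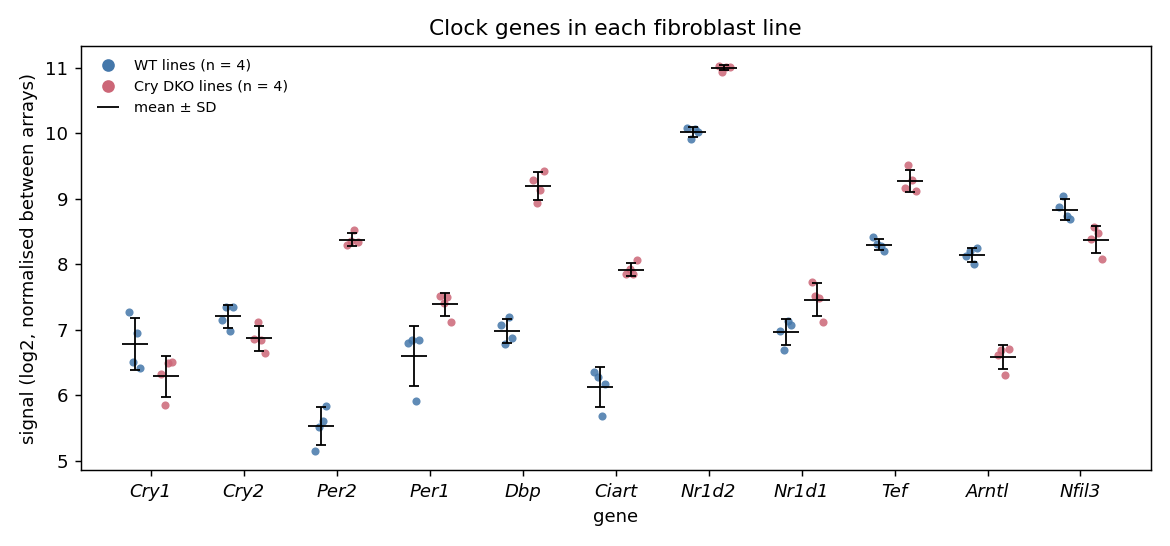
Signal (log2) of the 2 targeted genes and 9 clock genes in each WT (blue) and Cry DKO (red) line, 1 point per line, with black marks for mean ± SD. The Per2 and Dbp means rise by 2.84 and 2.21, and the Arntl mean falls from 8.14 to 6.58, with no overlap between the groups.

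The list of the positive arm of the clock and RORE targets, genes controlled by the NR1D and ROR receptors, had 8 tested members and did not pass as a list in the main test (camera adjusted p = 0.168), with a mean change of -0.23. It passed as lower in 3 of 22 alternatives: fry (adjusted p = 1.95e-05), each probe set tested (0.00753) and without WT replicate 2 (0.0489). It did not pass in the other 19, among them an estimated correlation (adjusted p = 0.293), a replicate block (0.218) and the other fits without 1 array. Arntl and the transcriptional repressor Nfil3 fell by 1.56 and 0.46, and Tipin, a protein of the replication fork, rose by 0.25. Leaving out 1 array ended the call of Nfil3 in 4 and that of Tipin in 5 of 8 fits. Adjusted over the list alone 1 rose and 3 fell. Clock itself had a difference of 0.00 (SE 0.09). In the list of circadian bZIP output and drug metabolism genes 2 of 7 members rose, Dbp and Tef (3 rose and 2 fell adjusted over the list alone), while Papss2 and Cyp1b1 had differences of -0.22 and -0.28 that did not pass. The median of this list was -0.01, its mean 0.41 and the main test was not passed (camera adjusted p = 0.20). It passed in 2 of 22 alternatives, fry (adjusted p = 0.00446) and each probe set tested (0.0337), and not in the others, such as an estimated correlation (0.298) or a replicate block (0.288).

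Genes of DNA replication and of mitosis rose in Cry DKO lines. In the DNA replication and S phase list 25 of 33 members rose and none fell (29 rose adjusted over the list alone), with a median change of 0.41 (camera adjusted p = 7.21e-22, and adjusted p = 0.0313 with an estimated correlation). Examples are Tk1, thymidine kinase, which rose by 0.57 (SE 0.07, limma adjusted p = 0.00196), Cdt1, a licensing factor of replication origins, by 0.53, Rrm2, the small subunit of ribonucleotide reductase, by 0.51 and Pcna, the sliding clamp of DNA polymerases, by 0.31. In the G2 and mitosis list 27 of 35 members rose and none fell (34 rose adjusted over the list alone), with a median change of 0.44 (camera adjusted p = 7.87e-27, and adjusted p = 0.0313 with an estimated correlation). The spindle checkpoint kinase Ttk rose by 0.79 (SE 0.09, limma adjusted p = 0.00079), Birc5, survivin, by 0.57, Top2a, a topoisomerase, by 0.56 and the checkpoint kinase Bub1 by 0.54. The mean over the 68 genes of both lists was 8.57 ± 0.07 (SD, n = 4) in WT and 8.99 ± 0.02 in Cry DKO lines. The macrophage markers rose in the same lines, by 0.74 at the median.

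The list of CDK inhibitors and G1 cyclins moved both ways and did not pass as a list (camera adjusted p = 0.715). Of its 16 members 4 fell, all inhibitors of cyclin-dependent kinases: Cdkn1c by 1.17 (SE 0.12, limma adjusted p = 0.000477), Cdkn2b by 0.52, Cdkn1a by 0.42 and Cdkn2a by 0.42. The inhibitor Cdkn2c rose by 0.48 (SE 0.10, limma adjusted p = 0.0149), Rbl1, a pocket protein of the retinoblastoma family, by 0.39 and Cdk2 by 0.37. Counts adjusted over the list alone were the same, 3 higher and 4 lower. Of 22 tested p53 targets, 4 fell and none rose (6 fell adjusted over the list alone; camera adjusted p = 0.00276, and adjusted p = 0.267 with an estimated correlation): Cdkn1a by 0.42, the antiproliferative gene Btg2 by 0.39, Eda2r by 0.31 and Ccng1, cyclin G1, by 0.16. The call of Eda2r ended in each of the 8 fits without 1 array, that of Ccng1 in 7, those of Cdkn1a and Btg2 in 3 each, and that of Rbl1 in 1. The macrophage markers rose by 0.74 in the same lines. With their mean as a covariate, a fit chosen after seeing the data, the p53 list did not pass (camera adjusted p = 0.291). Its mean change went from -0.16 (SE 0.05) to -0.049 (SE 0.05), so the estimate was smaller at a similar SE. The shift itself was not tested, and the covariate differs between the genotypes.

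**Figure D2:**
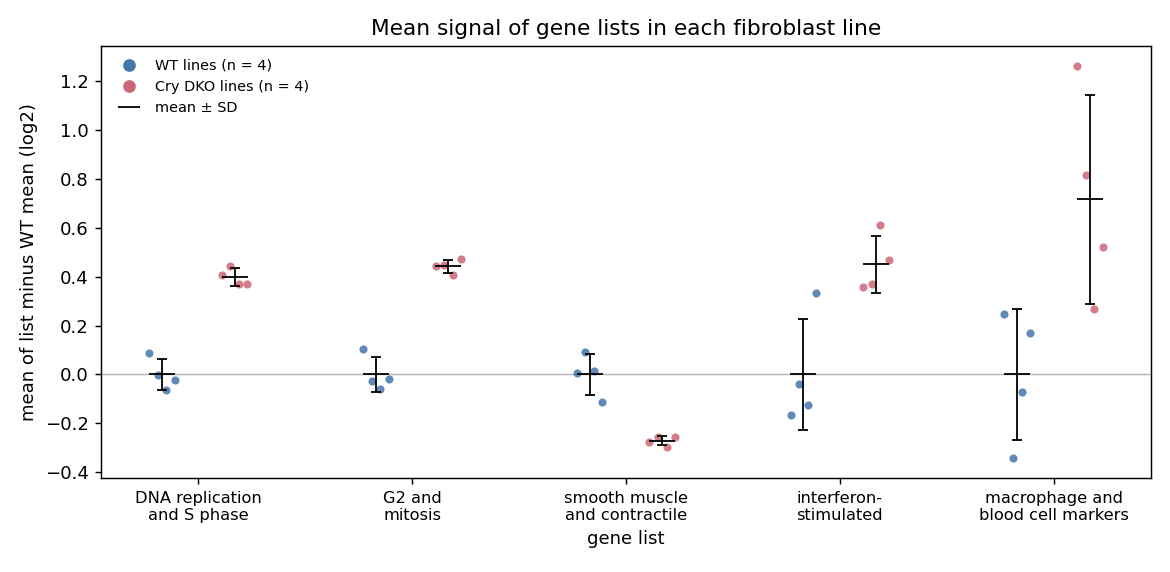
Mean signal of 5 gene lists in each line minus the WT mean of that list (log2), 1 point per line, WT blue and Cry DKO red, with black marks for mean ± SD (n = 4). The Cry DKO means lie 0.40 (S phase) and 0.44 (mitosis) above WT with little spread, and the macrophage marker means lie 0.72 above WT with an SD of 0.43.

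Markers of macrophages and blood cells rose. Of 17 tested markers 8 rose and none fell, and 15 rose adjusted over the list alone (camera adjusted p = 3.41e-10, and adjusted p = 0.293 with an estimated correlation, which was 0.867 between these genes). Lyz2, lysozyme, rose by 0.83 (SE 0.13, limma adjusted p = 0.00423), from 11.3 ± 0.22 to 12.2 ± 0.26 (SD, n = 4), Cd53 by 0.92, Cd14 by 0.92 and Csf1r, the receptor of the macrophage growth factor, by 0.84. The mean of the list was 8.66 ± 0.27 in WT and 9.37 ± 0.43 in Cry DKO lines. Interferon-stimulated genes rose as well, 8 of 14 members and none lower, the same adjusted over the list alone (camera adjusted p = 0.000838, and adjusted p = 0.297 with an estimated correlation). Rtp4 rose by 1.53 (SE 0.37, limma adjusted p = 0.0289), the immunoproteasome subunit Psmb8 by 0.93, the antiviral enzyme Oas1a by 0.92 and the RNA sensor Ddx58 by 0.49. Rtp4 had 5.75 ± 0.87 in WT lines, below the floor, where dim signals are less precise, and its groups overlapped. Without 1 array the call ended in 5 of 8 fits for Rtp4 and Ddx58, in 6 for Oas1a and in 3 for Psmb8. WT replicate 4 had the highest mean of this list among WT lines, 7.36 against 6.86 to 6.99 in the others. None of 15 tested NF-kappaB and inflammatory cytokine genes passed in limma, also over the list alone, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.466); Cxcl12 had a difference of -0.36 and Vcam1 one of 0.27.

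Genes of contractile cells fell. In the smooth muscle and contractile list 4 of 16 members fell and none rose (8 fell adjusted over the list alone; camera adjusted p = 9.14e-07, and adjusted p = 0.221 with an estimated correlation). Myh11, smooth muscle myosin heavy chain, fell by 0.85 (SE 0.14, limma adjusted p = 0.00493), Synpo2 by 0.54, Lmod1 by 0.44 and Myl9 by 0.22. The call of Lmod1 ended in 6 of the 8 fits without 1 array. In the list of collagens and fibroblast extracellular matrix 2 of 26 members fell, Lox, a crosslinker of collagen, by 0.24 and the collagen gene Col5a1 by 0.16, and the proteoglycan gene Vcan rose by 0.37. None of these 3 calls is stable: they ended in 8, 7 and 7 of the 8 fits without 1 array. Adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 0.000106, and adjusted p = 0.325 with an estimated correlation), and Fbln5 had a difference of -0.31 (limma adjusted p = 0.0536). The macrophage markers moved the other way in the same lines, by 0.74.

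Smaller increases were found in metabolic lists, beside the same rise of macrophage markers. Of 20 cholesterol synthesis genes 5 rose (6 adjusted over the list alone; camera adjusted p = 2.25e-05, and adjusted p = 0.267 with an estimated correlation), among them Stard4 by 0.39, Cyp51 by 0.33, Idi1 by 0.32 and Hmgcs1 by 0.23. Of 28 MYC targets and ribosome biogenesis genes 3 rose, the same over the list alone (camera adjusted p = 4.85e-06, and adjusted p = 0.267 with an estimated correlation): Rrp12 by 0.43, the transferrin receptor gene Tfrc by 0.38 and nucleolin, Ncl, by 0.20, while Fbl had a difference of 0.25 (limma adjusted p = 0.0875). Of 21 hypoxia (HIF) targets 3 rose (6 adjusted over the list alone; camera adjusted p = 0.000838, and adjusted p = 0.267 with an estimated correlation): Pdk1, a kinase that restrains pyruvate oxidation, by 0.53, Egln3 by 0.36 and the glucose transporter gene Slc2a1 by 0.27, while Bnip3 had a difference of 0.27 (limma adjusted p = 0.0647). Other probe sets of the called hypoxia genes gave smaller differences that did not pass when each probe set was tested. They were 0.43 and 0.21 for Pdk1, 0.20 for Egln3, and 0.12 and 0.09 for Slc2a1. Without 1 array the call ended in 6 of 8 fits for Rrp12, in 5 for Idi1, Hmgcs1, Egln3 and Slc2a1, and in 4 for Tfrc and Ncl. In the imprinted growth gene list Cdkn1c fell by 1.17 and the growth factor gene Igf2 rose by 0.76 (SE 0.14, limma adjusted p = 0.0109). The list as a whole was lower, with a median of -0.16 over 14 members (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.00547, and adjusted p = 0.17 with an estimated correlation), while Gnas and Impact had differences of -0.19 each that did not pass. With the macrophage mean as a covariate, chosen after seeing the data, this list did not pass (camera adjusted p = 0.0531). Its mean change was -0.19 (SE 0.05) before and -0.18 (SE 0.08) after, so the estimate hardly moved while its SE grew. Why the camera call ended was not tested.

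**Figure D3:**
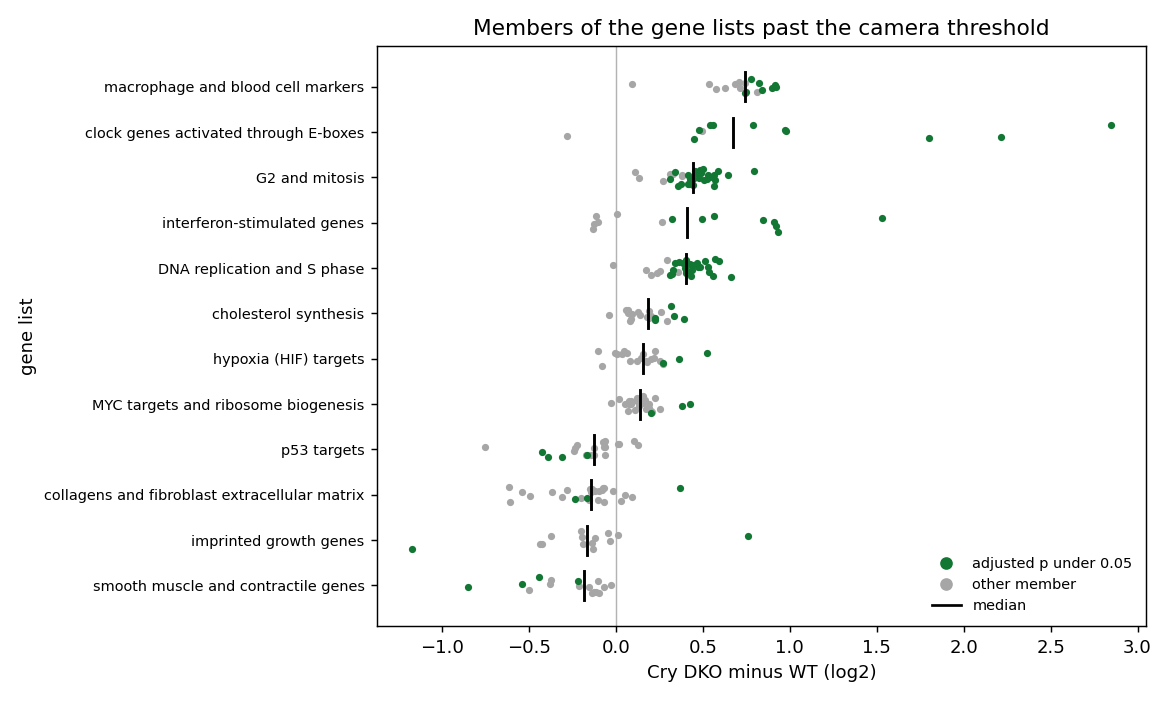
Difference between Cry DKO and WT lines (log2) for each tested member of the 12 gene lists that passed the camera test, 1 point per gene, green where the limma adjusted p is under 0.05 and grey otherwise, with a black line at the list median. The medians run from -0.18 in the smooth muscle list to 0.74 in the macrophage marker list, and most green points lie in the DNA replication, mitosis and clock lists.

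The remaining lists did not pass the main camera test. Of 13 glucocorticoid receptor targets 2 rose, Tsc22d3 by 0.51 and Per1 by 0.79, and 2 fell, Cdkn1c by 1.17 and the phosphatase gene Dusp1 by 0.33 (3 and 3 adjusted over the list alone; camera adjusted p = 0.553). Of 21 cAMP-CREB and immediate early genes 2 fell, Btg2 by 0.39 and Dusp1 by 0.33, the same over the list alone (camera adjusted p = 0.686), and Egr3 and Nr4a2 had differences of 0.62 and 0.40 that did not pass. Of 16 TGF-beta targets Bhlhe40 rose by 0.54 and Tgfb3 fell by 0.34 (1 and 2 over the list alone); the median was -0.06 and the mean 0.02 (camera adjusted p = 0.553), and Tgfbi and Tgfb1i1 had differences of 0.53 and -0.20 that did not pass. Of 20 HOX genes Hoxc9 fell by 0.55, the same 1 over the list alone (camera adjusted p = 0.523), while Hoxc8, Hoxc6 and Hoxd13 had differences of -0.36, -0.35 and 0.38. Without 1 array the differences ran from -0.44 to -0.22 for Hoxc6, from 0.25 to 0.59 for Hoxd13 and from 0.34 to 0.67 for Tgfbi. The call of Hoxc9 ended in 5 and that of Dusp1 in 3 of the 8 fits without 1 array. Of 25 genes of the unfolded protein response and ATF4 targets Psat1 rose by 0.28, the same 1 over the list alone (camera adjusted p = 0.237), while Herpud1, Sdf2l1 and Phgdh had differences of 0.20, 0.19 and 0.18. This list passed as higher in 3 of 22 alternatives: each probe set tested (camera adjusted p = 0.0437), without WT replicate 2 (0.0363) and the macrophage mean as a covariate, chosen after seeing the data (0.0124). It did not pass with an estimated correlation (0.56) or in fry (0.276), and its mean change of 0.028 was 0.0019 without Cry DKO replicate 4. None of 18 NRF2 and oxidative stress genes passed in limma, over all genes or over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.269) and Gsta4 at -0.53 and Srxn1 at -0.29.

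Markers of other cell types gave few calls. Of 7 adipocyte markers Cd36 rose by 1.14, the same 1 over the list alone (camera adjusted p = 0.269), and Cebpa, Fabp4 and Pnpla2 had differences of 0.44, 0.25 and -0.21. No marker passed in limma among 4 of skeletal muscle (2 at an unadjusted p under 0.05, which also fell over the list alone; camera adjusted p = 0.363; Acta1 -0.33, Des -0.38), 5 of neural and glial cells (1 at an unadjusted p under 0.05; camera adjusted p = 0.269; Ncam1 -0.27, Stmn2 -0.37) or 3 of cartilage and bone (1 at an unadjusted p under 0.05; camera adjusted p = 0.276; Col2a1 0.37, Sox9 0.28). Each of the adipocyte, neural and skeletal muscle lists passed in only 1 of 22 alternatives. These were each probe set tested for the adipocyte list, as higher, and the neural list, as lower (camera adjusted p = 0.0337 each), and the macrophage covariate, chosen after seeing the data, for the skeletal muscle list, as lower (0.04). Differences of single markers depend on single lines: without 1 array they ran from -0.53 to -0.16 for Stmn2, from -0.41 to -0.19 for Acta1, from 0.15 to 0.33 for Fabp4, from 0.29 to 0.68 for Cebpa and from -3.81 to -0.61 for Eif2s3y. Sox9 in WT and Egfl7 in Cry DKO lines lay below the floor. Lists with fewer than 3 tested members were not tested: endothelial markers (Egfl7 -0.29 and Flt1 -0.09), epithelial markers (Krt18 -0.30 and Krt19 0.02), Y-linked genes (Eif2s3y -2.21, SE 1.96) and erythroid and liver markers, of which 0 were tested. Signals of Xist and of Y-linked genes separated the lines by embryo sex, with 1 Xist-positive line among the WT and 2 among the Cry DKO lines.

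The last comparison asked whether genes near the targeted loci changed more often, since the lines derive from a mixed BL6/129 background. Within 10 Mb of Cry1 or Cry2, 20 of 232 tested genes were called (8.62%), against 852 of 9263 elsewhere (9.2%), an odds ratio of 0.931 (95% interval 0.554 to 1.48, p = 0.908 in Fisher's exact test). Each locus alone was tested after seeing the data. Near Cry1 12 of 175 genes were called (6.86%), an odds ratio of 0.727 (95% interval 0.366 to 1.31, p = 0.354 in Fisher's exact test). Near Cry2 8 of 57 were called (14%), an odds ratio of 1.61 (0.657 to 3.45, p = 0.244 in the same exact test). Within 20 Mb of Cry2 18 of 118 were called (15.3%, odds ratio 1.79, 95% interval 1.01 to 2.99, p = 0.0351 in Fisher's exact test). This did not pass after adjustment over the 6 windows (adjusted p = 0.211). Near Cry1, Itgb2, a leukocyte integrin, rose by 0.95 (SE 0.23, limma adjusted p = 0.0273), Pdxk by 0.67, Tmpo by 0.44, Gas2l3 by 0.36, Nup37 by 0.32 and Pwp1 by 0.20. Mterf2, a mitochondrial transcription factor, fell by 0.65 (SE 0.12, limma adjusted p = 0.00841). It is the called gene closest to Cry1 and had the largest fall near it, and an effect of the targeted allele on this neighbour was not tested. Fstl3 fell by 0.44, Adamtsl5 by 0.43, Cbarp by 0.42, Chst11 by 0.40 and Nuak1 by 0.39. Near Cry2, Selenoh rose by 0.39, Nup160 by 0.26 and Ckap5 by 0.25. Tfpi, an inhibitor of coagulation, fell by 0.62 (SE 0.11, limma adjusted p = 0.00833), Tnks1bp1 by 0.52, Creb3l1 by 0.50, Ctnnd1 by 0.32 and Slc39a13 by 0.23. The size of the Tfpi fall depends on the probe set. Its other probe sets gave -0.24, -0.20 and -0.16, which did not pass when each probe set was tested. Without 1 array the calls of Pwp1 and Slc39a13 ended in 8 of 8 fits, that of Ckap5 in 7, those of Gas2l3, Nup37, Cbarp, Nup160 and Tnks1bp1 in 6, those of Itgb2 and Ctnnd1 in 5, that of Fstl3 in 4 and that of Adamtsl5 in 1.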

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

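The tests on macrophage marker correlation, interferon-stimulated genes, Fcgr2b, gene families and the chromosome 1 stretch were chosen only after the results were seen, as were the fits with sex and macrophage markers. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many called genes as the genotypes. This was the real split itself with 873, and the highest of the others gave 1. That argues against a chance split as the source of the count, only as strongly as 35 splits can. The other splits mix the genotypes, which widens the spread within their groups, so low counts are likely there. A culture difference aligned with genotype was not tested by the splits.

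Markers of macrophages were higher in Cry DKO lines by 0.74 at the median, with list means per line from 8.92 to 9.92 in Cry DKO and from 8.31 to 8.90 in WT lines (p = 0.0286 in an exact two-sided permutation test, the smallest it can give). A larger share of macrophages in these cultures predicts that the markers deviate together from line to line, and their median pairwise correlation within genotypes was 0.897, while the abundant macrophage transcript Lyz2 was at 11.3 in WT lines already, so such cells may be present in both genotypes. Whether their share is the whole cause of the interferon list's rise stays open. With the macrophage mean as a covariate the rise stayed at 0.54 (95% interval 0.0059 to 1.08). That interval included 0 in 7 of the 8 fits without 1 array, and the macrophage means of the genotypes do not overlap. The slope between the list means within genotypes was -0.13 (interval -0.69 to 0.44), where 0.63 would be needed. This slope pools unlike correlations, 0.21 within WT and -0.89 within Cry DKO lines, and comes from the same fit. For Fcgr2b the macrophage share stays open too. The lowest lower 95% bound of its probe sets, 1.15, lies above the highest listed marker (0.92) but below the unlisted myeloid gene Trem2 (1.32). The sex of the lines left a median marker difference of 0.66, but the interval of the list mean (0.0026 to 1.26) is too wide to exclude it, and a change within macrophages was not tested.

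The rise of the DNA replication and mitosis lists was 0.43 at the median of 68 genes. Unequal numbers of male and female lines would bring it below 0.2 once sex is a term, and it stayed at 0.41 (95% interval of the list mean 0.32 to 0.49). A larger share of macrophages would do the same with the macrophage mean as a covariate, and it stayed at 0.36 (interval 0.23 to 0.51). These values argue against either as the whole cause. A larger share of cycling cells in Cry DKO cultures, from genotype or from culture age and density, is a candidate explanation that was not tested.

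Single lines stood apart from the 3 others of their genotype in 20 of 326 groups checked, and chance flags about 1 in 20. The lines apart had log2 signals of 9.29 for Bub1 (Cry DKO replicate 1), 12.7 for Ccng1, 10.3 for Cdkn2b and 7.12 for Egr3 (Cry DKO replicate 4), 9.97 for Col2a1 (Cry DKO replicate 3), and 10.9 for Nr1d2 and 7.20 for Synpo2 (Cry DKO replicate 2). In WT replicate 3 they were 7.48 for Cdkn2c, 11.4 for Cyp1b1 and 5.90 for Per1, in WT replicate 2 9.94 for Herpud1, 8.86 for Hoxc6 and 11.7 for Psat1, in WT replicate 4 8.29 for Nampt and 8.92 for Nup37, and in WT replicate 1 7.61 for Pdxk and 2.83 for Eif2s3y, a Y-linked gene in an Xist-positive line. List means stood apart for cAMP-CREB genes in WT replicate 4 (9.22), for the unfolded protein response in WT replicate 2 (10.3) and for circadian bZIP output genes in Cry DKO replicate 2 (8.71).

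Among 1920 probe sets above the floor that carry no single gene name and entered no comparison, 75 passed in limma, 37 higher and 38 lower. The probe set with the smallest p among them, which is unnamed here and was singled out after its value was seen, fell by 4.26 (SE 0.23, limma adjusted p = 3.34e-06). Of the 61 control probe sets 0 were called and 3 had an unadjusted p under 0.05 in limma, and 3' minus 5' control signals differed by -0.05 for actin and -0.01 for Gapdh (p = 0.286 and 0.514 in exact permutation tests).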

How the results depend on the processing

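The fits with sex and macrophage terms and of each locus alone were chosen after seeing the data. The macrophage means do not overlap between WT (8.31 to 8.90) and Cry DKO lines (8.92 to 9.92). Calls lost with them as a covariate may therefore reflect lost precision as well as macrophage share. The counts of called, higher and lower genes (873, 471 and 402) were 317, 199 and 118 with Student's equal-variance test. They were 520, 293 and 227 with sex as a term and 51, 22 and 29 with the macrophage mean as a covariate, and the cause was not tested. They were 211 at 1.5-fold and 1436 at an adjusted p of 0.10. Without 1 array, which leaves fewer samples, they ranged from 386 to 684, from 225 to 360 and from 161 to 329. Of the 99 called named genes, 58 kept their call without any 1 array and 41 lost it at least once. Calls of named genes ended for 55 with Student's test, for 24 with sex as a term and for 80 with the macrophage covariate. Other filters, normalisations, probe set rules and empirical Bayes settings gave 668 to 974 genes, all within 1.5 times of the count; with each probe set tested, 1113 of 16347 probe sets passed, from 894 genes. The replicate numbers were not taken to pair the lines. Same-numbered residuals correlated at 0.354, 0.132, 0.234 and -0.0214, and 3 of 4 WT and 3 of 4 Cry DKO lines correlated best with their own number. A replicate block gave 1050 genes, 810 of them also called in the main fit, so some calls changed both ways. Of 26 lists, 12 passed camera, 3 with an estimated correlation and 11 with fry; without 1 array 12 to 14 passed. With each probe set tested 17 passed: the positive arm, circadian output, unfolded protein response, neural and adipocyte lists were added. Fry added the first 2 of these and lost the collagen, interferon and macrophage lists (adjusted p = 0.0668, 0.0589 and 0.0512). With the macrophage covariate 11 passed: the p53 and imprinted lists no longer did (adjusted p = 0.291 and 0.0531), the unfolded protein response (mean 0.09, adjusted p = 0.0124) and skeletal muscle markers (-0.38, adjusted p = 0.04) did, and the macrophage list cannot be tested there. Cry1 and Cry2 stayed short of the threshold in every fit, and fell out under a filter at the 60th percentile. The odds ratio near Cry1 and Cry2 moved from 0.931 to 1.13 with a 20 Mb window (p = 0.494 in Fisher's exact test) and to 1.61 for Cry2 alone (p = 0.244). Signs turned in values that passed nowhere: cAMP-CREB genes at -0.0065, -0.014 and -0.013 (60th percentile filter, mean of probe sets, each probe set), glucocorticoid receptor targets at 0.0097 (each probe set), Krt19 at -0.060 to 0.10, TGF-beta targets at -0.043 to 0.044 and Flt1 at -0.20 to 0.031 without 1 array, and, with the macrophage covariate, Eif2s3y at 2.51, Krt19 at -0.27, Sox9 at -0.10, Tgfbi at -0.23, TGF-beta targets at -0.10 and NF-kappaB genes at -0.013; the cause was not tested. Low signal limits dim genes most, with an SD of 0.55 under a mean of 5. A pseudocount was not run.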

Other observations

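The scan along the chromosomes, the count with gene families reduced, and the tests of Cry1 and Cry2 alone were chosen only after the results were seen; the tests near both loci pooled and of neighbours changed at least 2-fold were set before. Called genes crowded on a stretch of chromosome 1 around Fcgr2b. In a window of 3 Mb, 11 of 26 tested genes were called where 2.39 would be by the overall share, 3 higher and 8 lower. Besides Fcgr2b (3.04), Arhgap30, a gene of blood cells, rose by 0.69 and the phosphatase gene Dusp12 by 0.34. Adamts4 fell by 1.23 (SE 0.11, limma adjusted p = 0.000173), the tight junction gene F11r by 0.85, Rgs4, a regulator of G protein signalling, by 0.86, the kinase gene Uhmk1 by 0.74, Olfml2b by 0.55, Nit1 by 0.49, Tomm40l by 0.48 and B4galt3 by 0.29. These genes were named after their values were seen.

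A window as full arose in a share of 0.00899 of 1000 random placements of the calls over tested genes, which argues against chance placement, though neighbours that share regulation are not independent; the next fullest window, around Ttk, had 5 of 8 (share 0.210). A stretch of 129 chromosome kept through the backcrosses is a candidate explanation, since strain variants can change the level of a gene or the fit of a probe in either direction. The wider tests give it no general support. Of 46 genes changed at least 2-fold, 10 had another within 2 Mb, where random draws gave a median of 6 and a 95th percentile of 11, and 8 had one after keeping 1 gene per family, so neither strain stretches nor gene families are decided by this count. Around the targeted genes pooled the odds ratio of 0.931, with its interval ending below 2, argues against a stretch with many called genes, as does the 0.727 near Cry1; near Cry2 alone it was 1.61 with an interval to 3.45, which leaves such a stretch open there; whether the chromosome 1 stretch differs in sequence between the lines cannot be read from expression values, and the genotype itself stays open as the source.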
